A study of Homo sapiens with 21 samples.

How the data were processed

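Poly(A) RNA of HCT-116 cells given serum EVs of patients with hepatocellular carcinoma (HCC+) or of healthy people (HCC-) at 1.2, 0.24 or 0.048 mg/mL, or no EVs (blank), was sequenced in 21 libraries, 3 for each of 7 groups. Per the labels, the cells were grown in DMEM with exosome-depleted serum, RNA was isolated with the RNeasy Mini kit and libraries were made with NEBNext Ultra II reagents. Per the labels, the authors trimmed reads with cutadapt 3.4, aligned them to GRCh38 with HISAT2 2.2.1 and counted them with featureCounts 2.0.1. The annotation release and the strand and multimapping settings are not given in the sources used here. The deposited table holds raw counts of reads per gene for 65065 Ensembl genes with the exon coordinates that featureCounts wrote. Symbols were found for 41967 identifiers, and 27406 genes had no count in any library.

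All libraries entered a single model with 7 group means in edgeR 4.0.16 under R 4.3.3, with TMM factors, genes kept by filterByExpr, robust dispersions and the quasi-likelihood F test, 2-sided, with 14 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. The 13 comparisons were HCC+ against HCC- at each dose and averaged over doses, each source and dose against the blank, the highest against the lowest dose for each source, and the difference of the source effect between these doses. The common biological coefficient of variation was 0.0885. Standard errors are the log2 fold change over the root of its F statistic. The design, 40 gene lists, the alternatives and the rule for named genes were set before the data were examined. Lists with at least 3 tested members, 38 of 40, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry beside it, and adjusted over the lists of a comparison. The counts of called members were also taken with p adjusted over the list alone.

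The rule named, for each comparison with calls, up to 5 rising and 5 falling genes with the largest log2 fold change among called genes with a mean of at least 1 log2 CPM and libraries that did not overlap. No overlap was asked for in the test of the difference between doses. For these largest changes only genes with a symbol were taken, and XIST and Y-linked genes were left out. The rule also named up to 4 called members with the smallest p of each list that passed or had at least 3 called members, and every called marker of another cell type. The rule named 965 pairs of a gene and a comparison, of which the texts give 212. Left out among others were 8 pairs whose direction turned under an alternative, and the part on alternatives gives 7 of them. Tonicity genes named in the closing section were chosen after their values were seen.

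The total count per library, 31.22 to 64.01 M, sets the precision for genes with few counts. Where a group held 3 counts or fewer, a ratio of counts with an exact 95% interval is given. For a group with 0 counts, the ratio to a floor of 3 counts over the group is given with the lower 95% limit. These ratios use library totals without TMM factors. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The method was tested on simulated data with the dispersions of these libraries. Of 19556 simulated genes 220 had a set change, and 18822 passed the filter. Of those changed by 1.5-fold, 2-fold and 4-fold, 61.4%, 82.9% and 96.7% were recovered, with 14 false among 182 calls. The simulation had few changed genes and no trends with GC content. So it does not test the method where many genes change or where libraries differ by GC content.

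The overlap of effects against the blank was taken in separate fits of the 9 libraries of each dose and set beside 20 simulated data sets in which no group differed. Other settings tried, as planned, were RLE size factors, no filter on low counts except at least 1 count, DESeq2 1.42.0, the replicate number as a block, only the groups compared, and each library left out in turn. Settings chosen after seeing the data were scaling to the total count alone, removal of each library's trends with GC content and gene length, and list tests and overlaps without each library. With the trends removed, list tests used log2 CPM in place of counts, so a changed list call can come from either change. GC content came from the GENCODE v29 transcripts and was known for 99.7% of tested genes, of which 12251 set the trends as natural splines. Other splits of the libraries were fitted with the same model. The replicate number joined no libraries across groups, since of 63 pairs with a shared number 1 had a correlation of residuals over 0.1. The figures were drawn with matplotlib 3.10.9 under Python 3.11.15.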

Results

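HCT-116 is a human colorectal carcinoma cell line of epithelial-like cells. The cells were given extracellular vesicles (EVs), membrane-bound particles that cells release, which had been isolated from human serum with the GlyExo-Capture method. The serum came from patients with hepatocellular carcinoma, a primary liver cancer (HCC+), or from healthy people (HCC-). EVs of each source were given at 1.2, 0.24 or 0.048 mg/mL, and cells without EVs served as the blank. Poly(A) RNA was sequenced in 3 libraries for each of the 7 groups, 21 libraries in all. The deposited values were counts of reads per gene, on GRCh38. The design sets EVs of HCC patients against EVs of healthy people and against control cells.

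The libraries held 31.22 to 64.01 M (mega) counts. The mean total (± SD, n = 3) was 49.9 ± 5.39 M for HCC+ at 1.2 mg/mL, 50.5 ± 3.43 M at 0.24 mg/mL and 46.6 ± 15.2 M at 0.048 mg/mL. For HCC- it was 50.5 ± 5.72, 48.6 ± 5.19 and 43.8 ± 8.38 M at the same doses, and for the blank 38.4 ± 6.30 M. Of 65065 annotated genes, 19556 passed the filter on low counts and were tested, and these held 99.96% of all counts. Levels are given in CPM, counts scaled to library size with TMM factors, as mean ± SD of 3 libraries. Log2 fold changes are given ± the standard error from edgeR's quasi-likelihood test over all 21 libraries, and genes are said to rise or fall where the Benjamini-Hochberg adjusted p was under 0.05. Genes given as the largest changes are the first among those that passed, had a mean of at least 1 log2 CPM and, except in the test of a difference between doses, had libraries that did not overlap between the groups. Genes without a symbol, XIST and Y-linked genes were not ranked. Groups of genes were lists written before the data were examined, tested with camera at a preset correlation between genes and again with an estimated one. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values rest on the spread between these libraries alone. They also do not say how many people gave the serum of a source. The first principal component held 34.6% of the variance and set the 6 libraries at 1.2 mg/mL, at -25.5 to -87.6, apart from all others, at 12.3 to 31.6.

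In cells given HCC+ EVs at 1.2 mg/mL, genes of amino acid synthesis and uptake were lower than in the blank. PSAT1, an enzyme of serine synthesis (ENSG00000135069, chromosome 9, positions 78297125 to 78330093), fell from 529 ± 22.6 to 158 ± 5.33 CPM, a log2 fold change of -1.74 ± 0.06 (adjusted p = 1.69e-19). PHGDH, which starts the same pathway, changed by -1.23 ± 0.06, and the amino acid transporter subunits SLC3A2 and SLC7A5 by -0.97 ± 0.07 and -0.99 ± 0.07. Of 18 tested genes of the amino acid and integrated stress response list, 14 fell and 0 rose, with a median log2 change of -0.98 (adjusted p = 2.71e-34, and adjusted p = 0.00215 with an estimated correlation). PCK2, the mitochondrial enzyme that makes phosphoenolpyruvate (ENSG00000100889, chromosome 14, positions 24094053 to 24110598), had the largest fall, at -2.18 ± 0.09. NIBAN1 (-1.84 ± 0.13), MEIOSIN (-1.80 ± 0.44) and CHAC1, which degrades glutathione (-1.78 ± 0.19), fell as well.

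Cell cycle genes fell and p53 target genes rose in the same cells. All 19 genes of the mitosis list fell, among them the cyclin CCNB2 (-0.91 ± 0.07), CDC20 (-0.72 ± 0.07) and the proliferation marker MKI67 (-0.54 ± 0.06). In the DNA replication list 17 of 20 genes fell and 1 rose, with RRM1, a subunit of ribonucleotide reductase, at -0.71 ± 0.07 and the helicase subunit MCM7 at -0.48 ± 0.06. The list tests gave adjusted p = 2.76e-18 for mitosis and 1.11e-10 for DNA replication, and with an estimated correlation adjusted p = 0.0533 for each. Of 19 p53 targets 13 rose and 0 fell (adjusted p = 1.11e-10, and adjusted p = 0.00727 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 198 ± 13.3 to 298 ± 2.06 CPM (0.59 ± 0.06). BTG2 changed by 0.95 ± 0.08, TP53INP1 by 1.57 ± 0.14 and BBC3, which promotes cell death, by 0.94 ± 0.11.

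Genes that build ribosomes fell with HCC+ EVs at 1.2 mg/mL, and genes of lysosomes rose. All 18 ribosome biogenesis genes fell, including MRTO4 (-0.68 ± 0.06) and the nucleolar protein gene NCL (-0.57 ± 0.06), with adjusted p = 5.44e-14 and adjusted p = 0.00727 with an estimated correlation. Falls were also found for 23 of 28 ribosomal protein genes (median -0.26), 14 of 21 nuclear genes of oxidative phosphorylation (median -0.26) and 5 of 11 heat shock genes. Those list calls gave adjusted p = 0.32, 0.0533 and 0.0707 with an estimated correlation. Cholesterol synthesis and uptake genes rose in 11 of 24 and fell in 2, with adjusted p = 0.325 with an estimated correlation. In the lysosome and autophagy list 10 of 16 genes rose and 1 fell (adjusted p = 0.000578, and adjusted p = 0.0181 with an estimated correlation), led by the sialidase NEU1 (0.76 ± 0.07) and GABARAPL1 (0.68 ± 0.08). TGF-beta and BMP targets rose in 7 of 10, as ID3 (0.91 ± 0.10), Wnt targets in 5 of 9, as NOTUM (1.02 ± 0.17), and targets of LXR, the sterol sensor, in 4 of 7, as the cholesterol exporter ABCG1 (1.81 ± 0.22). Each of these had adjusted p = 0.0533 with an estimated correlation. Interferon response genes rose in 11 of 21, with the RNA sensor RIGI at 0.78 ± 0.13 (adjusted p = 0.0707 with an estimated correlation). Adjusted over the list alone, rises numbered 16 for p53 and 6 for LXR, falls 18 for DNA replication, 25 for ribosomal proteins, 15 for oxidative phosphorylation and 6 for heat shock, and 1 interferon gene fell. The other counts given for this comparison were the same adjusted over the list alone. The Wnt list was not called with GC content and length trends removed, in a list test that used log2 CPM in place of counts. That lost call can come from either change. Leaving out blank replicate 3 ended the call of the cholesterol list (adjusted p = 0.0551).

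The largest rises against the blank were those of ANK1, an ankyrin of the membrane skeleton (3.95 ± 0.62), and SLC6A12, a transporter of betaine and GABA (ENSG00000111181, chromosome 12, positions 190077 to 214570; 3.89 ± 0.94). AOAH (3.00 ± 0.29), the histone gene H3C6 (2.66 ± 0.23) and CYP4F12 (2.65 ± 0.36) followed. The value of SLC6A12 was 2.74 without HCC+ replicate 1 and 4.92 without blank replicate 2. In all, 6444 genes passed, of which 3046 rose and 3398 fell. Changes of at least 1 on the log2 scale numbered 723 rises and 171 falls. Scaling to the total count alone moved the median log2 change of all tested genes by 0.12 and gave 4657 rises and 2069 falls. With it 14 ribosomal protein genes fell and 1 rose, and 3 heat shock genes fell and 2 rose.

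**Figure D1:**
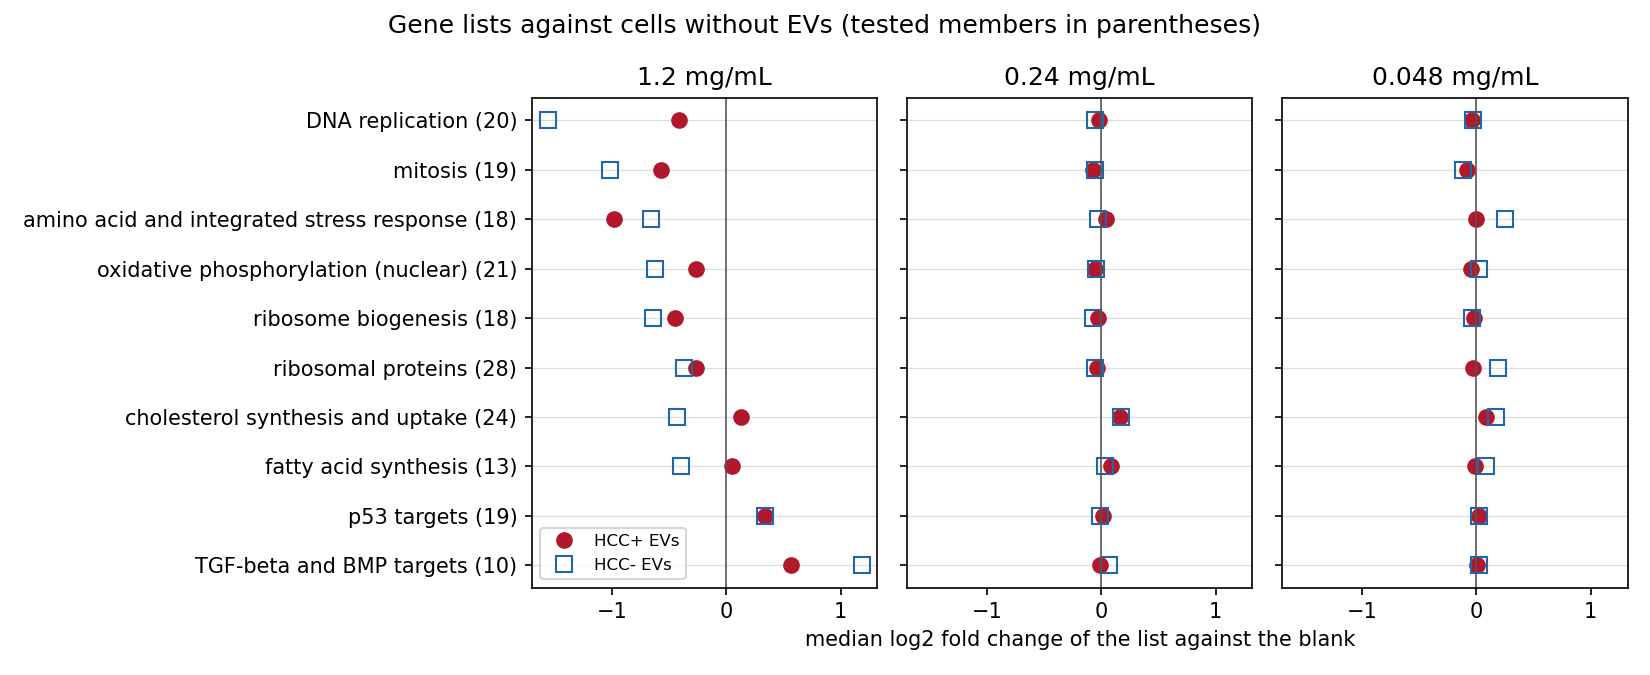
Median log2 fold change against the blank of the tested members of 10 gene lists, for HCC+ (filled circles) and HCC- (open squares) at each dose. At 1.2 mg/mL DNA replication stood at -0.42 for HCC+ and -1.56 for HCC-, and cholesterol synthesis and uptake at 0.13 and -0.43.

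In cells given HCC- EVs at 1.2 mg/mL, genes of DNA replication had the largest median change of the lists that passed. All 20 tested members fell, with a median of -1.56 (adjusted p = 5.69e-52, and adjusted p = 0.000347 with an estimated correlation). RRM2, the other subunit of ribonucleotide reductase (ENSG00000171848, chromosome 2, positions 10120698 to 10211725), fell from 464 ± 29.8 to 107 ± 9.23 CPM, a change of -2.12 ± 0.08. The replication genes MCM10, GINS2 and MCM4 changed by -2.06 ± 0.07, -2.04 ± 0.07 and -1.62 ± 0.06. All 19 mitosis genes fell too, with CDK1 at -1.67 ± 0.10 (-1.08 once GC content and length trends were removed) and CCNA2 at -1.52 ± 0.09 (adjusted p = 1.32e-17, and adjusted p = 0.0857 with an estimated correlation). Of single genes, RIBC2 (-3.29 ± 0.24), NIBAN1 (-2.63 ± 0.13), CDCA7 (-2.46 ± 0.10) and PCLAF, a partner of the replication clamp (-2.41 ± 0.16), were among those that fell most.

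Energy metabolism, ribosome biogenesis and amino acid genes also fell with HCC- EVs at 1.2 mg/mL. Nuclear genes of oxidative phosphorylation fell in 19 of 21, among them ATP5MC1 of ATP synthase (-1.45 ± 0.09) and NDUFV1 of complex I (-1.27 ± 0.08), with adjusted p = 0.0308 with an estimated correlation. Ribosome biogenesis genes fell in 17 of 18, as MRTO4 (-1.09 ± 0.06; adjusted p = 0.0296 with an estimated correlation). Falls were found for 14 of 18 amino acid and integrated stress response genes, with PSAT1 at -1.73 ± 0.06 and MTHFD2 of mitochondrial folate metabolism at -1.41 ± 0.08. Ribosomal protein genes fell in 25 of 28 and heat shock genes in 8 of 11, as the chaperonin HSPD1 (-1.26 ± 0.07), with 1 heat shock gene rising. In the cholesterol synthesis and uptake list 15 of 24 genes fell and 1 rose, with FDPS at -0.92 ± 0.07. Fatty acid synthesis genes fell in 9 of 13 and rose in 1, as ACACA (-0.54 ± 0.06). With an estimated correlation the adjusted p of these 5 lists was 0.109, 0.391, 0.0622, 0.254 and 0.119 in that order.

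Rises with HCC- EVs at 1.2 mg/mL were led by SLC6A12, from 0.0824 ± 0.0864 CPM in the blank to 13.9 ± 7.9 CPM (7.23 ± 0.81, adjusted p = 9.39e-07). Its blank libraries held 10 counts together, and without blank replicate 2 the value was 8.24. ANK1 (4.60 ± 0.62), the histone genes H2BC5 (3.67 ± 0.17) and H3C6 (3.53 ± 0.22) and CYP4F3 (3.24 ± 0.20) were next. TGF-beta and BMP targets rose in 8 of 10 and fell in 1, as SKIL (1.49 ± 0.16) and SMAD7 (1.21 ± 0.14). The p53 targets rose in 10 of 19 and fell in 1, with TP53I3 at 2.09 ± 0.12. Immediate early genes, which respond first to stimuli, rose in 7 of 16 and fell in 3, with FOSB at 2.05 ± 0.16 and JUN at 1.05 ± 0.11. These lists had adjusted p = 0.0622, 0.119 and 0.44 with an estimated correlation. In all, 10418 genes passed, 4844 rising and 5574 falling, with 1965 rises and 866 falls of at least 1 on the log2 scale. Scaling to the total count alone moved the median log2 change of all tested genes by 0.281 and gave 8128 rises and 3097 falls, and removing GC content and length trends gave 6338 rises and 4712 falls. The medians of the lists that fell were negative under both, although the counts moved. With the total count 11 cholesterol genes fell and 6 rose, 11 ribosomal protein genes fell and 2 rose, 5 heat shock genes fell and 2 rose, 6 fatty acid synthesis genes fell and 4 rose, and 10 amino acid genes fell and 2 rose. Of immediate early genes 13 rose and 1 fell with it, and 16 p53 targets rose. The fatty acid synthesis list was no longer called with the total count, nor the immediate early list without GC content and length trends or without blank replicate 1 or 3 or HCC- replicate 3 (adjusted p = 0.0995, 0.052 and 0.0669). The list test without the trends used log2 CPM in place of counts, so that lost call can come from either change. Adjusted over the list alone, 9 TGF-beta and BMP targets rose and 26 ribosomal protein genes fell, and the other counts given for this comparison were the same.

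Markers of other cell types and the long nuclear RNA NEAT1 moved with the 1.2 mg/mL dose, and so beside the lists above. NEAT1 rose from 70.2 ± 7.29 CPM in the blank to 137 ± 9.06 with HCC+ (0.96 ± 0.09) and 230 ± 6.34 with HCC- (1.71 ± 0.09). It is 1 of 4 tested genes in the list of signs of RNA quality, so its rise alone does not show a change of RNA quality. With GC content and length trends removed, 1 gene of this list rose with HCC+ and 2 rose with HCC-, and 0 fell. The list then did not pass camera on log2 CPM (adjusted p = 0.124 and 0.165). A change of RNA quality is thus neither shown nor excluded. The endothelial genes PECAM1 and VWF rose by 4.22 ± 0.73 and 1.60 ± 0.35 with HCC+ and by 5.52 ± 0.71 and 2.65 ± 0.34 with HCC-, and the collagen gene COL1A1 by 0.75 ± 0.11 and 0.99 ± 0.11. Of leukocyte markers, CD14 rose by 1.97 ± 0.60 and 3.43 ± 0.57, and HLA-DRA by 1.19 ± 0.31 and 1.56 ± 0.30. LYZ had 36 counts with HCC+ and 126 with HCC-, against 2 in the blank, ratios of 13.9 (95% counting interval 3.57 to 119) and 47.9 (13 to 400). SERPINA1 rose with HCC+ (0.58 ± 0.22) and the erythroid gene SLC4A1 with HCC- (2.74 ± 0.95). Of platelet markers, NRGN fell with each source (-0.59 ± 0.10 and -1.22 ± 0.10) and GP1BA fell with HCC- (-0.76 ± 0.20). Leaving out 1 library ended the call of CD14 in 2, of LYZ in 3 and of SERPINA1 in 4 of 6 fits with HCC+, and of SLC4A1 in 3 of 6 with HCC-. The call of SERPINA1 with HCC+ also ended without the filter on low counts. Without HCC+ replicate 1 CD14 was at 1.23, without blank replicate 1 PECAM1 was at 4.92 and 6.22, and without blank replicate 3 SLC4A1 was at 3.82. The blood cell transcripts HBB and PTPRC reached at most 11 and 4 counts in any library. No counts were found for PPBP, PF4, S100A8 and S100A9, where a count of 0 allows up to 3. The globin gene HBA2 passed the filter on low counts. A sum of 8 blood and liver transcripts that includes HBA2 reached at most 0.858 CPM at 1.2 mg/mL, scaled to the total count.

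HCC+ and HCC- EVs at 1.2 mg/mL changed many genes in the same direction against the blank. In fits of each dose with its 9 libraries, 2147 genes rose and 2522 fell with each source at 1.2 mg/mL, and 48 moved in opposite directions. Independent lists of the same lengths would share 710.2 and 759.4. The log2 changes correlated across genes at r = 0.792, against 0.533 in simulated groups without any change, because all comparisons share the blank libraries. The covariance was 0.491 against 0.0485 simulated, a difference of 0.442, or 0.428 when the share of the blank was taken from the spread of its libraries. At 0.24 and 0.048 mg/mL the covariances were 0.062 and 0.056 against 0.0443 and 0.0383 simulated, and 0 genes were shared by edgeR's test, or 413 at 0.048 mg/mL without blank replicate 2. Genes are not independent replicates, and the 3 blank libraries in both comparisons are too few to split.

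The direct comparison at 1.2 mg/mL asks whether EVs of patients act unlike those of healthy people, and replication and lipid synthesis genes were higher with HCC+. All 20 DNA replication genes were higher, with a median of 1.16 (adjusted p = 2.12e-71, and adjusted p = 0.00011 with an estimated correlation). Against the blank the median of this list was negative with both sources, so the higher values with HCC+ mostly mark a smaller fall. RRM2 stood at 321 ± 44.1 CPM with HCC+ and 107 ± 9.23 with HCC- (1.59 ± 0.08), and GINS2, MCM10 and MCM4 differed by 1.59 ± 0.07, 1.55 ± 0.07 and 1.18 ± 0.06. Of 24 cholesterol synthesis and uptake genes 22 were higher with HCC+ and 0 lower, with FDPS at 0.92 ± 0.07 and HMGCS1, which commits acetyl units to the pathway (ENSG00000112972, chromosome 5, positions 43287470 to 43313512), at 0.86 ± 0.09. Fatty acid synthesis genes were higher in 10 of 13, as ACLY (0.62 ± 0.06) and SCD (0.48 ± 0.05), and genes of fatty acid oxidation and PPAR targets in 9 of 13, as ACADM (0.74 ± 0.08) and HADHA (0.47 ± 0.06). Adjusted p with an estimated correlation was 0.018 for cholesterol, 0.00877 for fatty acid synthesis and 0.018 for fatty acid oxidation.

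Other lists differed between the sources at 1.2 mg/mL by the preset correlation alone. Higher with HCC+ were 18 of 21 oxidative phosphorylation genes, 13 of 19 mitosis genes (1 lower) and 11 of 18 hypoxia and glycolysis genes (1 lower), as LDHA (0.80 ± 0.09). Their adjusted p was 0.06, 0.339 and 0.514 with an estimated correlation. Against the blank all 19 mitosis genes and most oxidative phosphorylation genes fell with each source. For these 19 and 21 genes, higher with HCC+ thus mostly means a smaller fall. Lower with HCC+ were 6 of 16 immediate early genes (2 higher), with FOSB at -1.77 ± 0.15 and JUN at -0.94 ± 0.11, and 6 of 8 targets of YAP, a growth regulator, with CCN1 at -1.41 ± 0.13. Those lists had adjusted p = 0.339 and 0.225 with an estimated correlation.

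Single genes that were higher with HCC+ than with HCC- at 1.2 mg/mL included, among the largest, RIBC2 (2.75 ± 0.24), the exonuclease EXO1 (1.88 ± 0.10), RFC5, which loads the replication clamp (1.69 ± 0.10) and the histone chaperone ASF1B (1.60 ± 0.08). The largest negative values were those of SLC6A12 (-3.33 ± 0.54), MIR23AHG (-1.85 ± 0.14), FOSB, DNAH10 (-1.76 ± 0.17) and the histone gene H2BC21 (-1.74 ± 0.21). NEAT1 was lower with HCC+ (-0.75, adjusted p = 4.57e-08), the platelet marker NRGN was higher (0.63 ± 0.10), and CD14, VWF and PECAM1 were lower (-1.46 ± 0.47, -1.05 ± 0.30 and -1.30 ± 0.47). The calls of CD14 and PECAM1 ended in 3 and 4 of 6 fits without 1 library, and that of PECAM1 with DESeq2. Without HCC+ replicate 1, CD14 was at -2.21 and SLC6A12 at -4.49. In all, 6901 genes differed, 4411 higher and 2490 lower with HCC+, with 239 and 593 by at least 1 on the log2 scale. Scaling to the total count alone moved the median of all tested genes by -0.162 and gave 2342 higher and 4572 lower, and removing GC content and length trends gave 3611 and 4215. The medians of the replication, cholesterol and fatty acid lists were positive under both, and with the total count 11 oxidative phosphorylation genes were higher and 1 lower. Adjusted over the list alone, 14 mitosis and 12 hypoxia genes were higher, and the other counts given for this comparison were the same.

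**Figure D2:**
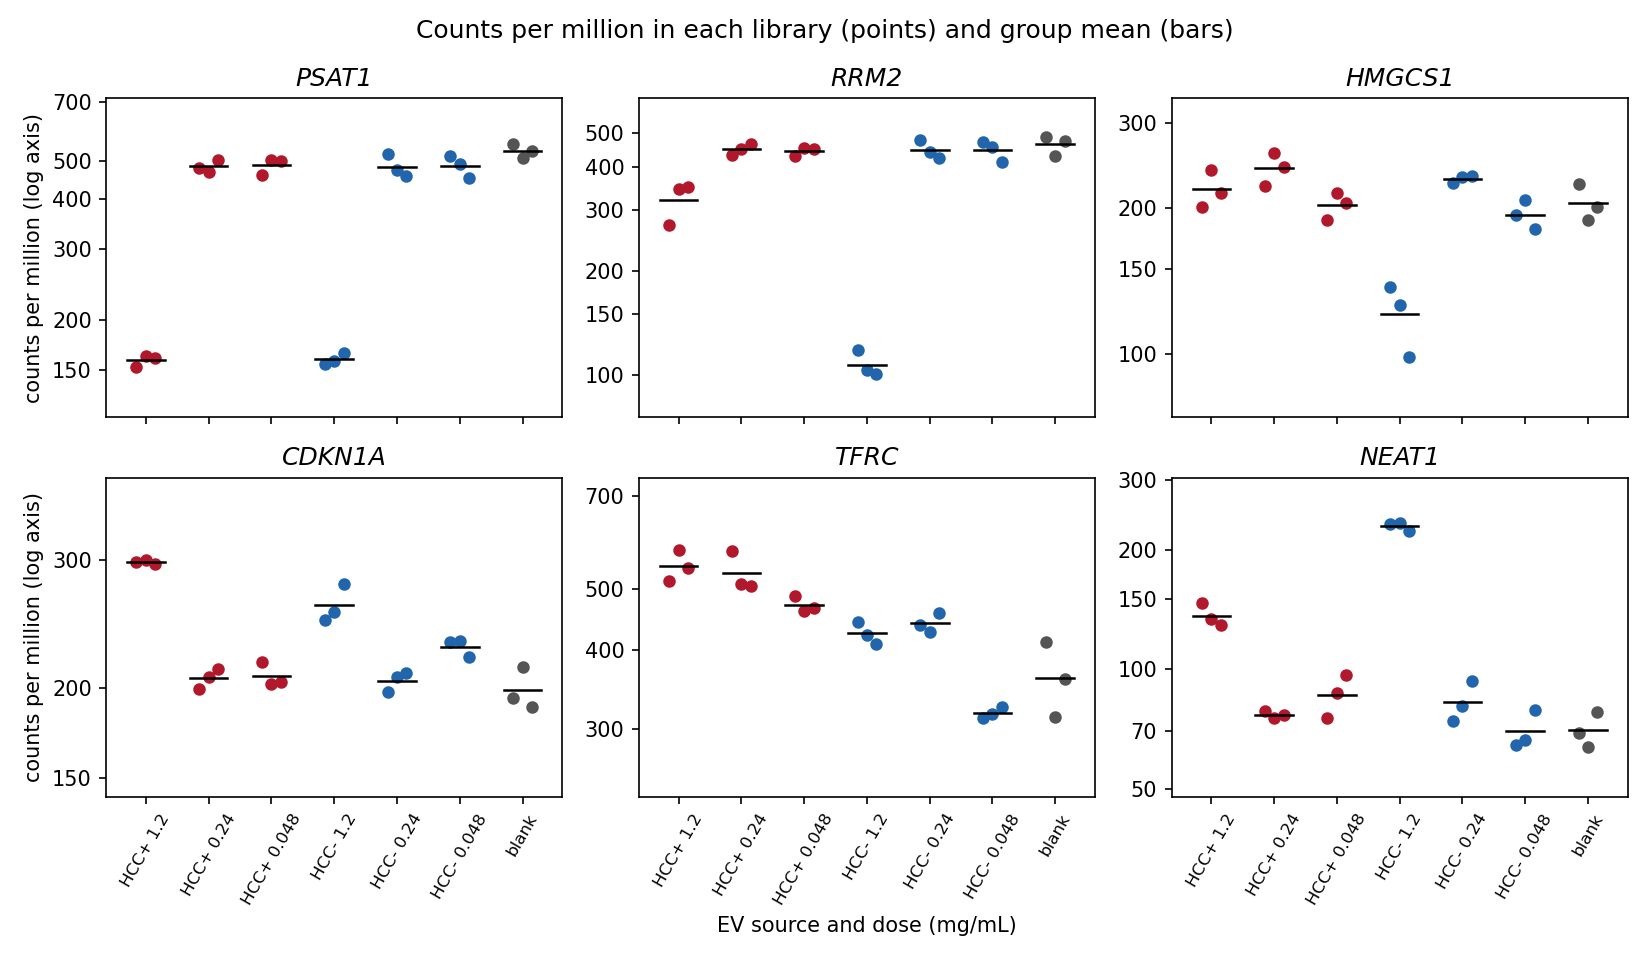
Levels in CPM of 6 genes in each of the 21 libraries, on log axes, by EV source and dose in mg/mL (HCC+ red, HCC- blue, blank grey), with a bar at the mean of the 3 libraries. RRM2 stood at 107 CPM with HCC- and 321 with HCC+ at 1.2 mg/mL, while PSAT1 stood at 160 and 158.

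Averaged over the 3 doses, HCC+ and HCC- EVs differed in the same lists, mostly through the values at 1.2 mg/mL. From the highest to the lowest dose the median difference was 1.16, 0.01 and -0.02 for DNA replication, 0.54, 0.01 and -0.06 for cholesterol, 0.41, 0.02 and 0.01 for fatty acid synthesis and 0.33, -0.02 and 0.04 for fatty acid oxidation. On average DNA replication genes were higher with HCC+ in 20 of 20, median 0.38, with MCM10 at 0.53 ± 0.04 (adjusted p = 0.00036 with an estimated correlation). Cholesterol genes were higher in 15 of 24, as IDI1 (0.34 ± 0.05), fatty acid synthesis genes in 9 of 13 and fatty acid oxidation genes in 7 of 13, with adjusted p = 0.0719, 0.0392 and 0.0447 with an estimated correlation. Adjusted over the list alone, 17 cholesterol, 9 fatty acid synthesis and 8 fatty acid oxidation genes passed. The largest positive values, of genes whose libraries did not overlap at each dose, were those of TFRC, the transferrin receptor that takes up iron (ENSG00000072274, chromosome 3, positions 196027183 to 196082096; 0.40 ± 0.04), the protease CTSK (0.40 ± 0.10), ALG10 (0.39 ± 0.09), the cell cycle regulator E2F2 (0.36 ± 0.04) and UBR7 (0.29 ± 0.04). GGACT (-0.42 ± 0.11), MC1R (-0.34 ± 0.10), ZSCAN9 (-0.34 ± 0.06), BMERB1 (-0.31 ± 0.05) and MORN4 (-0.26 ± 0.08) were lower. TFRC was at 543 ± 31.1, 529 ± 38.5 and 471 ± 13.3 CPM with HCC+ from the highest to the lowest dose, against 425 ± 17.3, 441 ± 15.7 and 318 ± 6.37 with HCC- and 361 ± 49.1 in the blank. The marker VWF was lower (-0.56 ± 0.19) and NRGN higher (0.19 ± 0.06) with HCC+. Leaving out 1 library ended the call of VWF in 14, of NRGN in 3 and of MORN4 in 1 of 18 fits, scaling to the total count that of NRGN, and omitting the filter on low counts that of MORN4. In all, 3028 genes passed, 2250 higher and 778 lower. Scaling to the total count alone gave 1173 higher and 1569 lower, with 5 fatty acid synthesis and 2 fatty acid oxidation genes higher, and removing GC content and length trends gave 1825 and 1457.

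At 0.24 mg/mL few single genes differed from the blank, while cholesterol genes lay above it as a group. With HCC+ EVs only TFRC passed, at 0.55 ± 0.07 (adjusted p = 0.000113), with 21 genes without HCC+ replicate 1 and 7 without blank replicate 2. With HCC- EVs 0 genes passed edgeR's test, or 1 without blank replicate 1, and HCC+ against HCC- gave 0 as well. The counts at an unadjusted p under 0.05 were 1193, 905 and 462, and DESeq2 gave 3, 0 and 0 calls. The cholesterol synthesis and uptake list had a median log2 change of 0.17 with HCC+ and 0.17 with HCC- against the blank. Its adjusted p was 2.07e-15 and 1.75e-15, or 0.0483 and 0.0464 with an estimated correlation. Adjusted over the list alone, 9 of its 24 genes passed with HCC+ and 9 with HCC-. The hypoxia and glycolysis list had medians of 0.40 and 0.37, with 0 genes called, 1 and 1 adjusted over the list alone, and adjusted p = 0.442 and 0.248 with an estimated correlation. At the preset correlation 6 lists passed with HCC+ and 13 with HCC-, and of these only the cholesterol list passed with an estimated correlation. Between the sources the cholesterol list passed without HCC+ replicate 1 (adjusted p = 0.0282). All comparisons against the blank share its libraries.

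At 0.048 mg/mL HCC+ EVs gave 0 genes against the blank by edgeR, or 1 without blank replicate 1, with 944 at an unadjusted p under 0.05 and 1 call by DESeq2. The preset correlation called 3 lists for it, cholesterol synthesis and uptake (median 0.08), hypoxia and glycolysis (0.15) and signs of RNA quality (0.82). Their adjusted p was 0.00221, 0.0356 and 0.00221, or 0.83, 0.83 and 0.723 with an estimated correlation. The call of the cholesterol list ended without blank replicate 3 (adjusted p = 0.12). That of signs of RNA quality ended without blank replicate 2 (0.25) or HCC+ replicate 3 (0.241). That of hypoxia ended without blank replicates 1 or 3 (0.441 and 0.213) or HCC+ replicates 2 or 3 (0.275 and 0.241), and without GC content and length trends. The list test without these trends used log2 CPM in place of counts, so that lost call can come from either change. HCC- EVs at this dose gave 3216 genes, 1620 rising and 1596 falling, with 42 and 33 by at least 1 on the log2 scale. The largest rises were those of ANGPTL4, an inhibitor of lipoprotein lipase (1.42 ± 0.40), MIR210HG (1.31 ± 0.27), AATK (1.09 ± 0.20), ANKRD37 (1.07 ± 0.24) and MAGEB17 (0.89 ± 0.27). HMGB1P10 (-0.98 ± 0.21), BCO2 (-0.85 ± 0.22), ZNF493 (-0.83 ± 0.26), PCGF3-AS1 (-0.83 ± 0.23) and TMEM170B (-0.77 ± 0.18) fell most. HMGB1P10 is a pseudogene and PCGF3-AS1 an antisense gene, and the strand and multimapping settings that decide which reads they receive are not given in the sources used here. Cholesterol genes rose in 10 of 24 and fell in 1, or 13 and 3 adjusted over the list alone (median 0.17, adjusted p = 0.00643, and adjusted p = 0.573 with an estimated correlation). Immediate early genes rose in 7 of 16, as JUN (0.46 ± 0.12), hypoxia and glycolysis genes in 6 of 18, and ribosomal protein genes in 13 of 28, with adjusted p = 0.573, 0.573 and 0.667 with an estimated correlation. Rises numbered 12, 12 and 16 adjusted over the list alone, with 2 falls of ribosomal protein genes. The count rested on single libraries: it was 1 without blank replicate 1, 12 without blank replicate 3 and 5726 without blank replicate 2. It was 1511, 706 and 1830 without HCC- replicates 1, 2 and 3, and 27 once the GC content and length trends of each library were removed. Then 1 cholesterol, 0 immediate early, 0 hypoxia and glycolysis and 1 ribosomal protein gene rose by edgeR. As groups these lists still passed camera upward at the preset correlation, with adjusted p = 1.68e-05, 0.00131, 1.07e-08 and 0.000236. Their medians were 0.096, 0.098, 0.415 and 0.066 in that order. These list tests used log2 CPM in place of counts.

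Between the sources at 0.048 mg/mL, 693 genes differed, 212 higher and 481 lower with HCC+. The largest positive values were those of the histone genes H3C6 (1.33 ± 0.24) and H2AC6 (0.97 ± 0.18), LACC1 (0.80 ± 0.22), METTL7A (0.79 ± 0.23) and ARV1 (0.66 ± 0.16). ALDOA, an enzyme of glycolysis (-0.95 ± 0.19), TEKT4P2 (-0.84 ± 0.23), LENG9 (-0.67 ± 0.19) and the metal-binding MT2A (-0.74 ± 0.18) and MT1E (-0.67 ± 0.15) were lower. ALDOA had only 7.74 ± 2.57 CPM in the blank, and its counts, like those of the histone and metallothionein families and of the pseudogene TEKT4P2, could be split with overlapping or near-identical genes. Ribosomal protein genes were lower in 6 of 28, or 17 adjusted over the list alone, as RPS15 (-0.35 ± 0.07; adjusted p = 0.541 with an estimated correlation). Iron handling genes were higher in 3 of 7, or 4 adjusted over the list alone, with TFRC at 0.57 ± 0.07 (adjusted p = 0.491 with an estimated correlation). The call of that list ended without HCC+ replicate 1 or HCC- replicate 2 or 3 (adjusted p = 0.0852, 0.0693 and 0.0653). Without a library the count was 2 or 3 (HCC- replicates 1 and 2), 536 (HCC- replicate 3), 258 (HCC+ replicate 1) and 3 or 4 (HCC+ replicates 2 and 3), and 2109 by DESeq2. It was 28 once GC content and length trends were removed, with 0 ribosomal protein genes and 1 iron handling gene by edgeR. As groups the ribosomal protein list (lower) and the iron handling list (higher) still passed camera at the preset correlation. Their adjusted p was 2.96e-07 and 0.00995, in tests that used log2 CPM in place of counts. Scaling to the total count alone gave 396 higher and 282 lower.

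Between the highest and the lowest dose of HCC+ EVs, genes of the amino acid, cell cycle and ribosome biogenesis lists fell and genes of the p53 and lysosome lists rose. Amino acid and integrated stress response genes were lower at 1.2 than at 0.048 mg/mL in 15 of 18, with PSAT1 at -1.62 ± 0.06 and CHAC1 at -1.82 ± 0.19 (adjusted p = 0.00087 with an estimated correlation). Mitosis genes were lower in 19 of 19 and ribosome biogenesis genes in 17 of 18, while p53 targets were higher in 14 of 19 and lysosome genes in 10 of 16. Their adjusted p was 0.051, 0.00545, 0.00545 and 0.00978 with an estimated correlation, and adjusted over the list alone 15 p53 targets passed, with the other counts the same. The largest rises were those of SLC6A12 (3.63 ± 0.86), ANK1 (3.22 ± 0.56), AOAH (2.49 ± 0.27), H2BC5 (2.21 ± 0.16) and CYP1A1, a xenobiotic-metabolizing enzyme (2.09 ± 0.16). PCK2 (-2.17 ± 0.09), MEIOSIN (-2.10 ± 0.43) and NIBAN1 (-1.64 ± 0.12) fell most beside CHAC1 and PSAT1. The other-cell markers HLA-DRA (0.80 ± 0.29), COL1A1 (0.68 ± 0.11), VWF (1.45 ± 0.34) and PECAM1 (3.92 ± 0.68) rose, as did NEAT1 (0.66, adjusted p = 8.91e-07), and NRGN (-0.50 ± 0.10) fell. Leaving out 1 library ended the call of HLA-DRA in 5 of 6 fits. Without HCC+ replicate 1 at 1.2 mg/mL SLC6A12 was at 2.47, and without HCC+ replicate 1 at 0.048 mg/mL it was at 4.28 and ANK1 at 3.88. In all, 5544 genes passed, 2625 higher and 2919 lower at 1.2 mg/mL, or 3838 and 1805 when scaled to the total count alone, which moved the median by 0.098.

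With HCC- EVs the same contrast was led by DNA replication genes, lower at 1.2 than at 0.048 mg/mL in 20 of 20 (median -1.51, adjusted p = 0.000495 with an estimated correlation). Oxidative phosphorylation genes were lower in 20 of 21, ribosomal protein genes in 28 of 28, cholesterol genes in 18 of 24 and hypoxia and glycolysis genes in 16 of 18, with adjusted p = 0.0286, 0.261, 0.124 and 0.329 with an estimated correlation. FDPS changed by -1.12 ± 0.07, LDHA by -0.91 ± 0.09 and EGR1, an immediate early transcription factor, by -2.74 ± 0.22. Of cholesterol genes 19 fell adjusted over the list alone, and the other counts were the same. The largest rises were those of SLC6A12 (6.41 ± 0.73), ANK1 (4.47 ± 0.60), H3C6 (3.87 ± 0.23), H2BC5 (3.57 ± 0.17) and the inositol transporter SLC5A3 (3.42 ± 0.22). MEIOSIN (-3.26 ± 0.44), RIBC2 (-3.12 ± 0.24), NIBAN1 (-2.67 ± 0.13) and MIR210HG (-2.58 ± 0.28) were the largest falls beside EGR1. NEAT1 rose (1.72 ± 0.09), as did the markers PECAM1 (4.72 ± 0.64), VWF (1.84 ± 0.32), CD14 (2.80 ± 0.53), HLA-DRA (1.64 ± 0.30) and COL1A1 (0.75 ± 0.11), and LYZ was at least 36.4-fold higher than the floor of 3 counts over the 0.048 mg/mL group. KDR (-1.79 ± 0.63), TF (-1.39 ± 0.57), NRGN (-1.36 ± 0.10) and GP1BA (-0.56 ± 0.20) fell. Leaving out 1 library ended the call of KDR in 2, of TF in 4 and of GP1BA in 2 of 6 fits, and without HCC- replicate 3 at 0.048 mg/mL ANK1 was at 5.58. The calls of TF and GP1BA ended with scaling to the total count, that of GP1BA also without GC content and length trends, and that of TF also with the replicate block and with only the groups compared. Without the filter on low counts the call of TF ended. In all, 10334 genes passed, 4867 higher and 5467 lower. With the total count alone the median moved by 0.292 and the counts were 8382 and 2979, with 19 ribosomal protein genes lower and 3 higher and 11 cholesterol genes lower and 3 higher, and removing GC content and length trends gave 6631 and 4822.

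The test of the difference asks whether the gap between the sources itself differed between 1.2 and 0.048 mg/mL, and it did for replication and lipid synthesis genes. All 20 DNA replication genes, 20 of 24 cholesterol genes and 8 of 13 fatty acid synthesis genes had a larger HCC+ minus HCC- value at 1.2 mg/mL, with medians of 1.25, 0.57 and 0.38. These were 20, 21 and 11 adjusted over the list alone, and the adjusted p was 0.000206, 0.0307 and 0.0127 with an estimated correlation. GINS2 differed by 1.62 ± 0.10, FDPS by 1.03 ± 0.10 and ACLY by 0.70 ± 0.08. The largest positive values were those of RIBC2 (2.81 ± 0.32), MIR210HG (2.11 ± 0.38), EXO1 (1.85 ± 0.14), SLC22A31 (1.85 ± 0.18) and ASF1B (1.81 ± 0.11), and the largest negative those of H2BC21 (-2.31 ± 0.32), H3C6 (-2.20 ± 0.31), DNAH10 (-2.06 ± 0.26), CMYA5 (-1.86 ± 0.34) and MIR23AHG (-1.79 ± 0.21). NEAT1 (-1.05 ± 0.12), CD14 (-2.0 ± 0.74) and NRGN (0.86 ± 0.14) passed too, the call of CD14 ending with only the groups compared and in 7 of 12 fits without 1 library, with values of -0.61 to -2.75. In all, 4750 genes passed, 3257 positive and 1493 negative. With the total count alone the median moved by -0.193 and the counts were 1631 and 3219, with 5 fatty acid synthesis genes positive and 1 negative, and removing GC content and length trends gave 2900 and 2938.

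**Figure D3:**
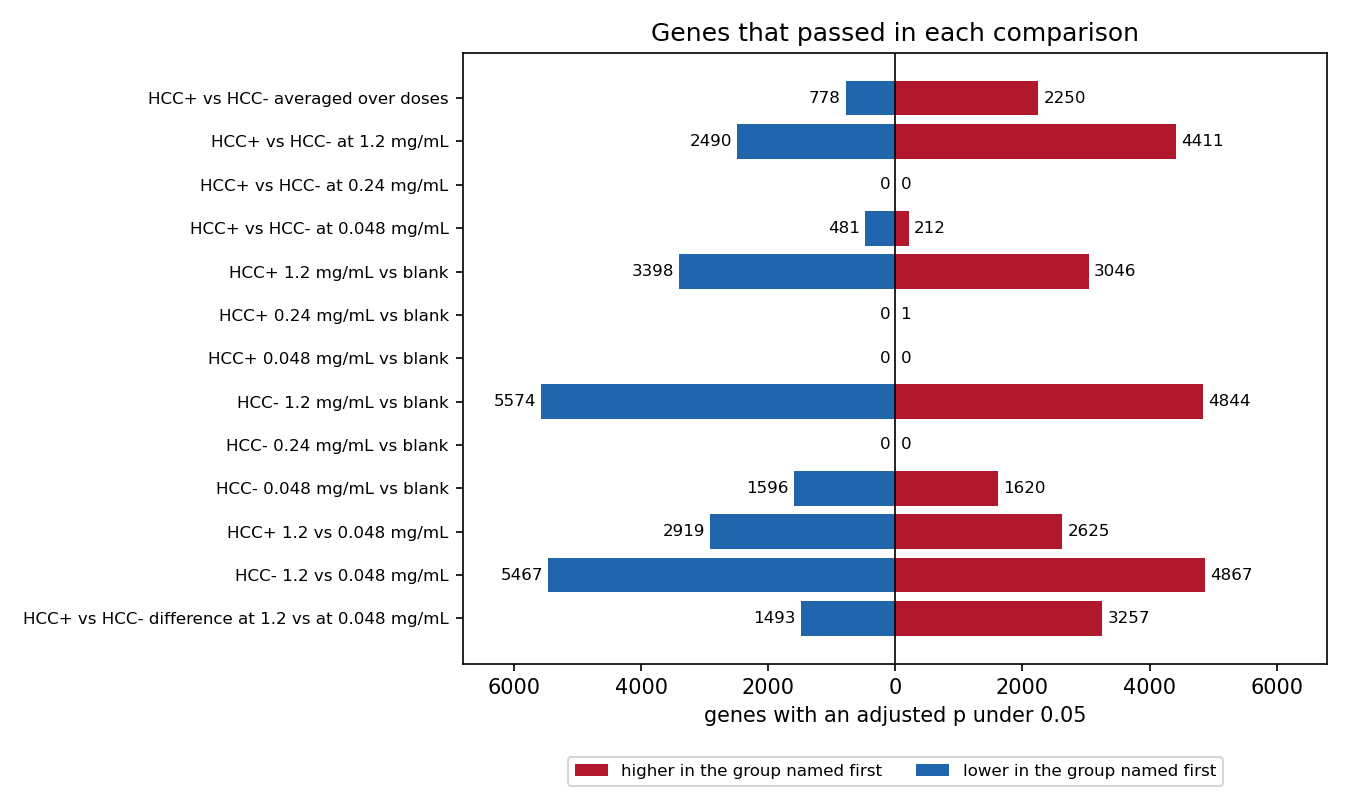
Number of genes past an adjusted p of 0.05 in each of the 13 comparisons, with genes higher in the group named first to the right of 0 and lower genes to the left. The comparisons at 0.24 mg/mL hold 1 gene at most, and HCC- at 1.2 mg/mL against the blank holds 10418.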

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

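The splits of the libraries and the tests of evenly spread DNA, of genes far from expressed ones and of blood and liver RNA were chosen after the result was seen, and the other tests of this part before it. The source effect differed between doses. By the test of the difference itself, the HCC+ minus HCC- value at 1.2 mg/mL was unlike that at 0.048 mg/mL in 4750 genes. The median difference was 1.249 for DNA replication, 0.566 for cholesterol synthesis and uptake and 0.382 for fatty acid synthesis. Of 100 splits of the libraries 2 gave as many genes, the real one included, a share under 0.05, and the highest other split gave 4959. The splits moved libraries between the sources within each dose. So the share bears on a source difference at either dose, and decides nothing on whether it differed between the doses. List tests at the preset correlation gave 13 list calls, and 10 of 100 splits gave as many, with 15 in the highest other, so chance is not excluded for that number. The split with 4959 genes kept the 3 libraries of each source together and exchanged the names of the sources at 1.2 mg/mL, so it too rests on the real groups.

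Counts outside the tested genes rose with the highest dose. The 45509 genes too low to be tested held 425 ± 52.8 CPM with HCC+ and 713 ± 29.5 with HCC- at 1.2 mg/mL (SD, n = 3), against 315 ± 36 in the blank. With all libraries thinned to the same depth, 27040 ± 31.4 genes had a count with HCC- and 24860 ± 384.8 with HCC+ at 1.2 mg/mL against 23142 ± 451.7 in the blank, so greater depth leaves an excess of 8.63 SD of the blank with HCC-. In what follows, CPM of silent genes and of blood and liver transcripts are scaled to the total count without TMM factors. Silent genes more than 100 kb from expressed genes held 6.69 CPM together at 0.24 mg/mL. They rose in HCC- libraries at 1.2 mg/mL by 4.88 ± 0.46 times against 0.24 mg/mL, and by 4.53 in the lowest library. This argues against transcription past gene ends as the source of the counts in these far genes. It does not cover the other untested genes, which held most of the untested counts. Silent genes within 10 kb downstream of expressed genes rose by 4.47 ± 0.29 on the same strand and 3 ± 0.26 on the opposite strand. The rise on the same strand over that far away was 0.92 on average and 0.89 in the lowest library, under the bound of 1.2 set beforehand. That bound was poorly chosen, since the levels at 0.24 mg/mL already differed, at 3.37, 3.64 and 0.42 CPM per Mb of exon for same strand, opposite strand and far. The counts added were 11.7, 7.29 and 1.63 CPM per Mb, so near expressed genes such transcription and genomic DNA cannot be told apart. DNA spread evenly over the genome would add equal counts per kb of exon, yet 6.96 to 7.56 times as many were added near expressed genes. This argues against evenly spread DNA as the only source of the counts near and far. Evenly spread DNA as the source of the far counts stays open, as does unevenly spread DNA. Abundant blood and liver transcripts, 8 in all, summed to 0.191 CPM in the blank, 0.56 with HCC- and 0.592 with HCC+ at 1.2 mg/mL, at most 0.858 in any library of that dose. A small amount of such RNA could be carried by the EVs, but the untested genes rose by far more and more with HCC- than with HCC+, which argues against it as the source of most of these counts. A cellular response to the dose, which the design could produce, stays open and was not tested.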

How the results depend on the processing

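Of the 965 pairs of a gene and a comparison that the rule named, 8 turned direction under an alternative, and these were left out of the other texts for that reason. The values of 7 are given here. So no gene given there turned, by choice of the genes, and no list call turned. Medians of lists without a call did: for HCC- at 1.2 mg/mL against the blank iron handling went from -0.06 to 0.23 with the total count and 0.16 with GC and length trends removed. For HCC+ against HCC- at 0.048 mg/mL DNA replication went from -0.02 to 0.02 with the total count and fatty acid synthesis from 0.01 to -0.03 with the trends removed. With scaling to the total count STAT3 went from 0.14 to -0.02 for HCC+ against HCC- at 1.2 mg/mL, FTH1 from -0.26 to 0.02 for HCC- at 1.2 mg/mL against the blank and MT-CO3 from -0.27 to 0.02 between doses of HCC-. With GC and length trends removed ME1 went from -0.21 to 0.04, CDKN1A from 0.20 to -0.01, SEL1L from -0.22 to 0.00 and HSPH1 from -0.20 to 0.07 for HCC- at 0.048 mg/mL against the blank. None of the 8 passed after turning.

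Of 3091 gene values under alternatives 2910 kept their call and 181 lost it, touching 37 of 218 results. Of 1098 list values 1014 kept their side of the threshold, 70 lost their call and 14 gained one, touching 53 of 86. Most list calls that were lost, 42 of 70, were lost with an estimated correlation, which left 26 list calls over all comparisons where the preset gave 142. Scaling to the total count, removal of GC content and length trends, and list tests and overlaps without a library were chosen after seeing the data. RLE size factors kept all 17 counts within 1.5 times.

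The counts that moved most were those at 0.24 and 0.048 mg/mL, and the cause was not tested except for GC content. HCC+ against HCC- at 0.048 mg/mL, 693 genes, gave 2109 by DESeq2, 28 with GC and length trends removed, 1483 without the filter, 3641 with only the groups compared and 1091 with the replicate block. HCC- at 0.048 mg/mL against the blank, 3216 genes, gave 27 with the trends removed and 1976 with only its groups. HCC+ at 0.24 mg/mL against the blank, 1 gene, gave 3 by DESeq2, 8 with the trends removed, 25 without the filter and 2 with only its groups. HCC+ at 0.048 mg/mL, 0 genes, gave 1 by DESeq2, 1 with the trends removed, 3 without the filter and 1 with the total count. HCC- at 0.24 mg/mL, 0 genes, gave 2 with the trends removed and 9 without the filter, and HCC+ against HCC- at 0.24 mg/mL gave 1 with the trends removed.

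Without 1 library, counts ranged from 2193 to 3424 averaged over doses, from 5322 to 6464 for HCC+ against HCC- at 1.2 mg/mL, from 0 to 0 at 0.24 mg/mL and from 2 to 536 at 0.048 mg/mL. Against the blank, they ranged from 4920 to 6640, from 1 to 21 and from 0 to 1 for HCC+ from the highest to the lowest dose, and from 9433 to 10203, from 0 to 1 and from 1 to 5726 for HCC-. They ranged from 4031 to 5130 and from 9192 to 9812 between doses of HCC+ and HCC-, from 3816 to 4650 for the difference, and from 126 to 155 for list calls. Genes shared by both sources against the blank ranged from 3178 to 5133, from 0 to 0 and from 0 to 413.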

Other observations

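In this part the tests of dose order, of normalization and of other splits, and the removal of GC content and length trends, were chosen after results were seen, and the other tests before the result each measures. Single members of 5 lists changed with EVs at 1.2 mg/mL, while none of these lists passed camera against the blank at this dose with all libraries. SGK1, a kinase gene induced by glucocorticoids, rose with HCC+ (1.19 ± 0.16) and HCC- (1.81 ± 0.15), while FKBP5, another glucocorticoid target, fell (-0.49 ± 0.07 and -1.19 ± 0.07). TSC22D3 rose with HCC- (1.35 ± 0.12). CYP1A1, a target of the aryl hydrocarbon receptor, rose with HCC- (2.61 ± 0.17), as did its repressor AHRR (1.49 ± 0.38). MT1E and MT2A, which bind metals, fell with HCC- (-1.60 ± 0.16 and -1.57 ± 0.18), and FTL, a ferritin subunit, fell (-0.51 ± 0.06). STRA6, a receptor for retinol binding protein, rose (3.85 ± 0.78), from 5 counts in the blank, and was at 4.47 without blank replicate 3. With HCC- the numbers that rose and fell were 3 and 1 of 6 glucocorticoid targets (4 and 1 adjusted over the list alone), 3 and 1 of 6 aryl hydrocarbon receptor targets, 1 and 3 of 5 metallothionein and zinc genes, 1 and 2 of 7 iron handling genes and 4 and 1 of 5 retinoid and vitamin D targets. The last 4 were the same adjusted over the list alone. The iron handling counts turned to 4 and 1 with the total count and 3 and 1 without GC content and length trends, its median going from -0.06 to 0.23 and 0.16. In that order adjusted p was 0.165, 0.112, 0.15, 0.761 and 0.467 with HCC- and 0.482, 0.0938, 0.105, 0.482 and 0.116 with HCC+. The aryl hydrocarbon receptor list passed with HCC+ without HCC+ replicate 1 (adjusted p = 0.042) or 3 (0.0439). The test fry, which does not set a list against other genes, called all 5 with HCC-, and all but iron handling with HCC+.

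Members of the epithelial list moved both ways. The epithelial splicing factors ESRP1 and ESRP2 fell with HCC- at 1.2 mg/mL (-0.82 ± 0.07 and -0.56 ± 0.07), as did the tight junction gene CLDN7 (-0.71 ± 0.08), while CLDN4 rose (1.51 ± 0.12). In the epithelial list 8 of 12 genes fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.132, and 0.0417 without GC content and length trends). With the total count 5 fell and 4 rose, with a median of -0.01 in place of -0.29. Of mesenchymal genes 7 of 12 rose, the same adjusted over the list alone, with FN1, which encodes fibronectin, at 0.57 ± 0.08 (adjusted p = 0.0325, and adjusted p = 0.208 with an estimated correlation). Of endoplasmic reticulum chaperones HSP90B1 fell with HCC- (-1.05 ± 0.07), in a list in which 9 of 15 fell and 2 rose, or 3 rose adjusted over the list alone (adjusted p = 0.0325, and adjusted p = 0.119 with an estimated correlation). That call ended without GC content and length trends (adjusted p = 0.118) and with the total count, by which 5 fell and 6 rose. List tests without the trends, that of the epithelial list included, used log2 CPM in place of counts. Their changed calls can come from either change.

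HCC- EVs at 0.048 mg/mL differed from the blank in 3216 genes. The changes correlated across tested genes with GC content (Spearman 0.548) and weakly with gene length (-0.106), genes not being independent replicates. Removing the trends of each library left 27 calls, 19 of them among the 3216, and the median size of the change in the called genes went from 0.308 to 0.08, so calls ended because the changes became smaller. Signed by their direction at 0.048 mg/mL, the same genes had a median change of 0.308, 0.058 and 0.146 at 0.048, 0.24 and 1.2 mg/mL. The ratio of 0.189 between 0.24 and 0.048 mg/mL decides nothing on an effect ordered by dose, since the genes were chosen at 0.048 mg/mL and the blank is shared. Leaving out blank replicate 1 gave 1 call and leaving out blank replicate 3 gave 12, and library differences in GC content, largest in blank replicate 1 with 47.36% of its deviation explained, are a candidate explanation, while an effect of the EVs, ordered by dose or not, stays open.

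Genes of osmolyte transport and synthesis rose at 1.2 mg/mL. SLC6A12 changed by 3.89 ± 0.94 with HCC+ and 7.23 ± 0.81 with HCC-, the inositol transporter SLC5A3 by 1.8 and 3.02, and AKR1B1, which makes sorbitol, by 0.44 and 2.16. With the total count the smallest of these in HCC- was 2.45, which decides nothing, since that scaling adds the same shift to every gene. ALB, the most abundant liver transcript, reached 0.114 CPM in HCC- libraries where SLC6A12 was at 10 CPM or more, which argues against liver RNA. Both of these CPM values are scaled to the total count without TMM factors. A hyperosmotic medium at the highest dose may raise such genes: 10 further tonicity genes had a median of 0.76 with HCC- and 0.39 with HCC+, at percentiles 100 and 99.8 of 10000 random lists. Of these genes 7 rose and 1 fell with HCC-, and 5 rose and 0 fell with HCC+. HSPA4L fell with HCC- (-0.48), and NFAT5 changed by 0.22 with HCC- and 0.01 with HCC+. SGK1, among those that rose, is also a member of the glucocorticoid list. The value with HCC+ missed the bound of 0.5 set before the test, and no osmolality is given, so this explanation and a response to the EVs themselves cannot be told apart. The call of AKR1B1 with HCC+ ended in 4 of 6 fits without 1 library, with the replicate block, without the filter on low counts and without GC content and length trends.

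For 2 groups of 3 libraries only 10 splits exist, too few for a share under 0.05. The real count and the highest other were 6901 and 3 for HCC+ against HCC- at 1.2 mg/mL, 0 and 0 at 0.24 mg/mL and 693 and 0 at 0.048 mg/mL. Against the blank they were 6444 and 0, 1 and 566, and 0 and 0 for HCC+ from the highest to the lowest dose, and 10418 and 0, 0 and 718, and 3216 and 118 for HCC-. Between doses they were 5544 and 1 for HCC+ and 10334 and 0 for HCC-. The splits with 566 and 718 genes at 0.24 mg/mL point to a structure of the libraries that the groups do not define. Averaged over doses 2 of 100 splits gave as many genes as the real 3028, the real one included, a share under 0.05, with 3924 in the highest other. That split exchanged the names of the sources at 1.2 mg/mL, kept them at 0.048 mg/mL and moved 2 libraries at 0.24 mg/mL. The splits moved libraries within each dose, so the share bears on a source difference at any dose, not on one shared by all doses. List tests at the preset correlation also passed in other splits. Averaged over doses 2 of 100 splits gave as many list calls, the real number being 15 and the highest other 16. The real number of list calls and the highest other were 16 and 13, 0 and 7, and 7 and 8 for HCC+ against HCC- from the highest to the lowest dose. Against the blank they were 15 and 12, 6 and 8, and 3 and 6 for HCC+, and 17 and 13, 13 and 6, and 6 and 7 for HCC-. Between doses they were 14 and 14 for HCC+ and 17 and 12 for HCC-.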
